A study of Mus musculus with 6 samples.

How the data were processed

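Gene expression was measured in whole testes of juvenile mice at postnatal day 21 on 1-colour Affymetrix arrays, with 1 array per sample. The 6 samples fall into 2 groups by their titles: 3 Nxf2 knockout (KO) samples and 3 wild-type (WT) samples. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on an RNeasy column and amplified by in vitro transcription with biotinylated nucleotides. The labels do not say how many animals gave each sample, so p-values measure the spread between these samples only.

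The deposited table holds 1 signal intensity per probe set and array on a linear scale, and MAS5 is named in the submitters' processing notes without a version. MAS5 combines the perfect-match and mismatch probes of a probe set and multiplies each array by 1 factor. In the deposited intensities the mean without the lowest and highest 2% was 150.0 on every array. Detection calls and scanner files were not used here, so no background limit per probe set was used. The number of arrays (3 per group) limits the precision.

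The table lists 45101 probe sets on 6 arrays, with no missing value and none at or below 0. The 64 control probe sets were left out of the tests. Of the other 45037, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 are unnamed here. Symbols were updated through Entrez identifiers against the RefSeq table of GRCm38.p6, which held 34741 of the 34945 (99.4%). That table also placed genes on chromosomes. The build behind the probe set annotation is not given in the sources used here, so no coordinates are printed. Genes were named only from probe sets with 1 symbol.

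The filter, the tests, the gene lists and the rule for named genes were fixed before the data were examined. Signals were transformed to log2(signal + 7), where 7 is the 25th percentile of all deposited values, so a fold change of a dim probe set is understated. Probe sets were tested if their mean over all 6 arrays reached the 40th percentile of probe set means, a signal of 20.5, which left 27022. Of these, 22970 have 1 symbol and represent 12971 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, no covariate), and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets. Log2 fold changes are KO minus WT and are given with limma's moderated standard error (SE). Group values are means of the deposited signal ± SD.

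The fixed rule for named genes took Nxf2 first. It then took, per direction, the 12 genes with the largest fold change among called probe sets whose 3 KO values lay all above or all below the 3 WT values, with 1 probe set per gene (lowest p) and a symbol that is not an accession, a Gm number or a RIKEN clone name. From each gene list it took the 2 to 4 measured members of lowest p. In total 23 gene lists were fixed from textbook knowledge, none of them chosen on these samples. They covered 6 germ cell stages, Sertoli, Leydig, peritubular myoid, immune, endothelial and red blood cells, epididymis, fat and skeletal muscle as neighbouring tissues, and 8 pathways or gene groups. A gene in a list was represented by its probe set with the highest mean over all arrays. The 22 lists with at least 5 measured genes were tested with camera (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the 22 lists), with camera under an estimated correlation and with fry as alternatives. All measured X-linked genes were tested in the same way. The intervals, the tests of single chromosomes and the tests of the closing section were added later. Intervals of medians are 95% bootstrap intervals over genes (10000 draws). Genes in a list are not independent replicates.

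The alternatives were quantile normalization, median centring of each array, pseudocounts of 1 and of 39 (the median of all values), no dim filter and a filter at the 60th percentile, eBayes without the trend, array weights, the replicate number as a block, and each array left out in turn. For the lists, the mean of all probe sets of a gene was also tried.

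The fit was tested on simulated arrays for the KO against WT comparison, with the real means and residual spread of 27022 probe sets. It recovered 35.8% of 67 probe sets changed by 0.5 on the log2 scale, 84.4% of 64 changed by 1 and all 64 changed by 2. In that simulation 5 of 147 calls (3.40%) were false, and no call was made when nothing was changed. The list test, run on 12953 simulated genes, called the 1 list of 25 genes raised by 0.3 and none of the other 9 lists. The simulated probe sets and genes were drawn independently of each other. Both runs therefore do not show how often correlated probe sets, or lists of correlated genes, are called falsely.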

Results

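The transcriptomes of 3 Nxf2 KO and 3 WT testes were compared at postnatal day 21, an age at which the submitters found similar testis weights in both genotypes. Nxf2 is an X-linked germ cell paralogue of the mRNA export receptor gene Nxf1. At this age the first wave of spermatogenesis is under way, and the testis holds spermatogonia, spermatocytes and the first round spermatids among its somatic cells. The median deposited signal lay between 37.1 and 40.9 on the 6 arrays. Spearman correlations over the tested probe sets were 0.985 to 0.992 between KO arrays, 0.980 to 0.991 between WT arrays and 0.965 to 0.983 between the genotypes. The ratio of the 3′ to the 5′ control probe set, which rises as RNA degrades, was 1.90 ± 0.157 in KO and 2.04 ± 0.138 in WT for Actb, and 1.43 ± 0.0237 in KO and 1.5 ± 0.105 in WT for Gapdh (SD, n = 3 each).

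The targeted gene was measured first. The only Nxf2 probe set fell from a signal of 366.9 ± 23.6 in WT to 117.7 ± 12.4 in KO (SD, n = 3 each), a log2 fold change of -1.59 ± 0.0999 (SE) with the lowest p of all probe sets (limma, adjusted p = 0.000488). The fall was 3.0-fold, and each KO array lay below each WT array. Whether its probes lie inside the deleted part of the gene is not given in the sources used here, so the signal left in KO is reported as measured. The related genes Nxf3, with a log2 fold change of 0.070 (adjusted p = 0.367), and Nxf1 (adjusted p = 0.953), both singled out after their values were seen, did not pass the test.

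More probe sets fell than rose in KO testes, and the falls were deeper. Of 27022 probe sets, 2024 changed: 1414 fell and 610 rose in KO (limma, adjusted p under 0.05). These calls covered 1151 genes that fell and 484 that rose. In size, 208 called probe sets fell more than 2-fold, against 11 that rose more than 2-fold. Centring each array on its median shifted the split to 1509 falls and 353 rises, and array weights turned it to 3446 falls and 3771 rises. With the replicate number as a block the split was nearly even, at 2330 falls and 2173 rises. In 2019 of the 2024 calls the 3 KO values did not overlap the 3 WT values, a separation seen in 33.9% of all tested probe sets and expected by chance in 10%. The number of calls depended on single arrays: it was 164 without WT replicate 1, 1146 without WT replicate 2, 1045 without WT replicate 3, 1139 without KO replicate 2 and 1020 without KO replicate 3. Without KO replicate 1 it was 1547, with 388 rises.

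Among the 12 genes with the deepest falls, Llcfc1, whose product is needed for sperm to fuse with the egg, fell 8.12-fold, from 113.4 ± 58.3 in WT to 9.60 ± 14.1 in KO. Capza3, a spermatid actin-capping subunit, fell 6.31-fold, and Txndc8, a spermatid thioredoxin, 6.20-fold. Smcp, encoding a cysteine-rich protein of the sperm mitochondrial capsule, fell 6.06-fold, from 208.4 ± 112.9 to 26.5 ± 15.5. Hils1, a spermatid linker histone, fell 6.01-fold, and Akap4, the X-linked main protein of the sperm tail's fibrous sheath, 5.58-fold. Scp2d1 fell 5.92-fold, Tmco2 5.92-fold, Izumo3 5.90-fold, Ddi1 5.56-fold, Lyzl1 5.52-fold and Kif2b, a kinesin, 5.51-fold. All 12 had adjusted p values between 0.00617 and 0.0210. With 11 of the 12 at a KO mean below the dim limit of 20.5, these folds on the log2(signal + 7) scale depend on the pseudocount: Akap4 ranged from -3.97 to -1.06 on the log2 scale over the alternatives. Of these 12 and the 12 largest rises, 17 of the 23 still tested lost their call without WT replicate 1, 6 without KO replicate 2, 5 without KO replicate 3, 3 without WT replicate 3 and 2 each without KO replicate 1 and WT replicate 2, with adjusted p values of up to 0.159.

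Among the genes that the rule admits, which leaves out RIKEN clone names, the 12 largest rises were smaller than the 12 deepest falls. Mid1, an X-linked ubiquitin ligase gene, rose 4.61-fold, from 14.4 ± 12.1 in WT to 82.7 ± 16.2 in KO, and Erdr1 rose 2.93-fold, from 231.8 ± 121.4 to 637.1 ± 57.9. Star, which carries cholesterol into mitochondria for steroid synthesis, rose 2.01-fold, from 144.9 ± 40.2 to 298.7 ± 90.0. Zbtb16 (PLZF), a transcription factor of undifferentiated spermatogonia, rose 1.91-fold, from 153.6 ± 7.35 to 299.3 ± 19.2, with an SE of 0.0876 on the log2 scale and an adjusted p of 0.00273. Ccng1, the p53 target cyclin G1, rose 1.93-fold, Car3, a carbonic anhydrase abundant in fat and muscle, 1.93-fold, and Cd36, a fatty acid transporter gene, 1.94-fold. Mgl2, a macrophage lectin, rose 1.99-fold, Zfp36l2, an mRNA decay factor, 1.98-fold, Defb15, a beta-defensin, 2.33-fold, Aldh18a1, which serves proline synthesis, 2.30-fold, and Anxa4 1.93-fold. Their adjusted p values lay between 0.00273 and 0.0444. The other measured probe sets of these genes all had the same sign, but among them only that of Zbtb16 was also called. None of the other 4 probe sets of Aldh18a1 passed. Mid1, Defb15, Mgl2 and Cd36 had WT means below the dim limit, so their folds also depend on the pseudocount: Mid1 ranged from 1.21 to 2.74 on the log2 scale over the alternatives. Every one of the 12 kept its direction when each array was left out.

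**Figure D1:**
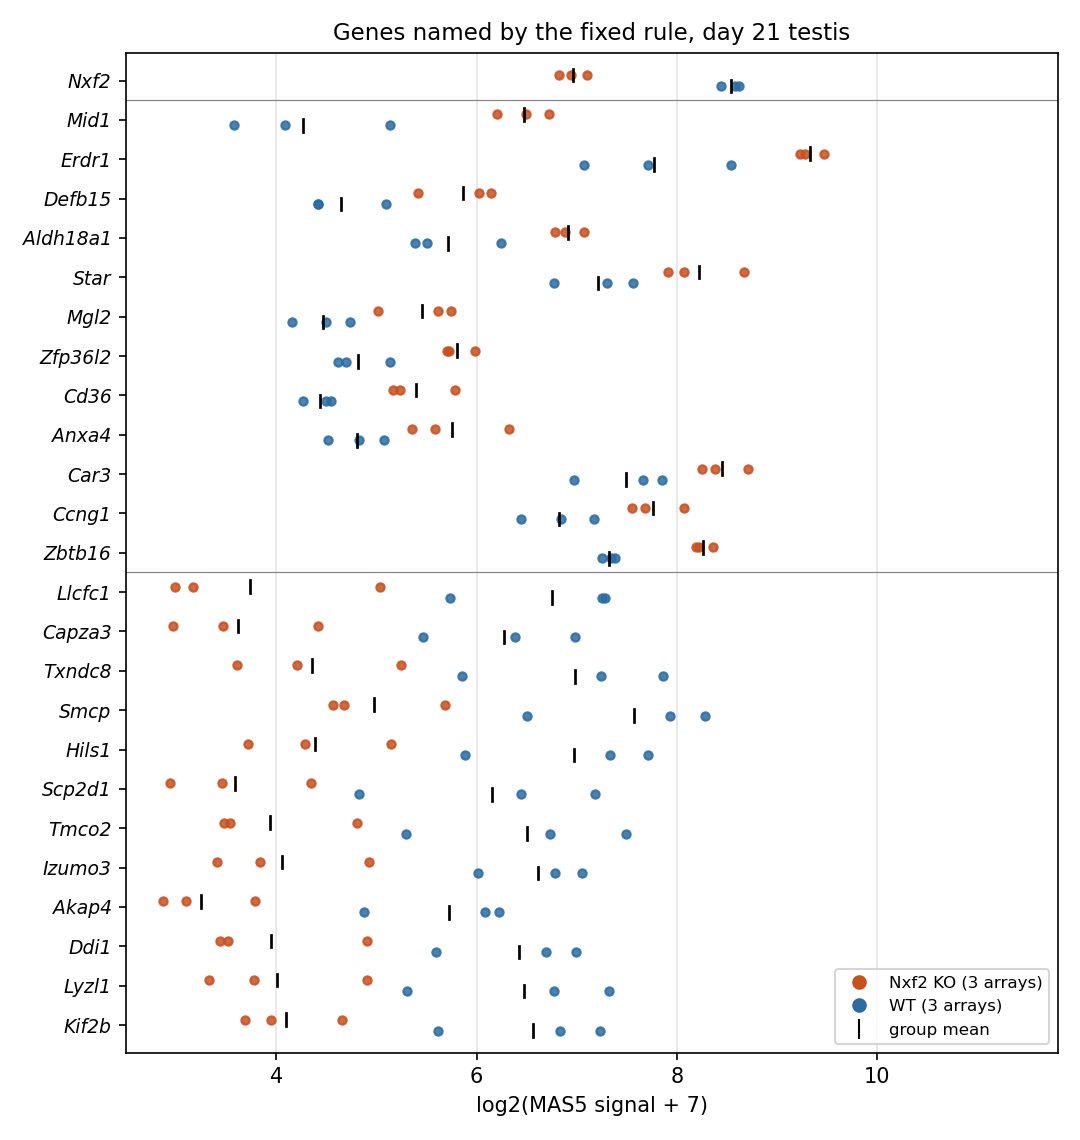
Signal of Nxf2 (top), the 12 genes with the largest rises (middle) and the 12 with the deepest falls (bottom), as log2(MAS5 signal + 7) on the horizontal axis, with 1 point per array (3 KO, 3 WT) and a black tick at each group mean. The KO points of every gene lie all above or all below the WT points, and the WT points of the falling genes are widely spread.

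Genes of spermatids were lower in KO as a group. Those of pachytene spermatocytes had a smaller median fall, with an interval that overlapped that of the elongating but not that of the round spermatid list. In the list of round spermatid genes 23 of 26 measured members fell and none rose (25 fell when adjusted over the list alone), with a median log2 fold change of -0.96 (95% interval -1.35 to -0.61). Acrv1, an acrosomal protein gene, fell from 136.8 ± 67.4 to 20.6 ± 12.7, a log2 fold change of -2.36 ± 0.375 (SE, adjusted p = 0.00884). Actl7b, an actin-like gene of spermatids, fell by 0.84 on the log2 scale (adjusted p = 0.0033), Tekt2, a flagellar tektin, by 0.69 and Zpbp2, of the acrosomal matrix, by 0.34. In the list of elongating spermatid genes 11 of 22 fell and none rose (16 fell when adjusted over the list alone), with a median of -0.62 (-1.71 to -0.18). Odf1, a sperm tail outer dense fibre gene, fell from 141.5 ± 63.5 to 21.8 ± 11.5, and Dnajb3 and Akap3 fell by 0.59 and 1.44 on the log2 scale. Capza3, also in this list, is given above. Relative to the mean of the WT arrays, WT replicate 2 lay nearest to the KO arrays: its median was -0.45 in the round and -0.44 in the elongating list, against 0.13 and 0.052 in WT replicate 1 and 0.33 and 0.49 in WT replicate 3. The KO medians were -1.13 to -0.79 in the round and -0.68 to -0.63 in the elongating list. Tnp1, Tnp2 and Prm1, which package sperm DNA and were singled out after their values were seen, did not pass: Tnp1 had a signal of 17.7 ± 3.27 in KO and 29.0 ± 15.6 in WT, Tnp2 one of 29.2 ± 8.0 and 28.5 ± 5.27, and Prm1 one of 28.9 ± 4.46 and 28.2 ± 4.05. In both groups these signals lay near the dim limit of 20.5, so they do not show that these genes were unchanged. In the list for pachytene spermatocytes and meiotic divisions all 24 members had lower means (23 after quantile normalization), 9 fell (13 when adjusted over the list alone) and the median was -0.21 (-0.32 to -0.12). Pgk2, the germ cell phosphoglycerate kinase, fell from 856.6 ± 10.7 to 581.1 ± 34.4, and Aurkc, Adam3 and Ccna1, the male germ cell cyclin A1, fell by 0.48, 0.32 and 0.42. By camera the adjusted p was 1.39e-15 for the round spermatid list, 2.34e-09 for the elongating spermatid list and 2.22e-07 for the pachytene list. With an estimated correlation these were lost: adjusted p = 0.199, adjusted p = 0.199 and adjusted p = 0.374 in the same order. By fry all 3 lists passed (adjusted p = 0.0234, 0.0338 and 0.0476 in that order).

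Of 32 genes of meiotic recombination and synapsis, 1 passed the test. Tex11, an X-linked meiotic gene, rose by a log2 fold change of 0.29 (adjusted p = 0.0325), and none of the other 31 members passed the test. Stag3, a meiotic cohesin gene, had a log2 fold change of -0.19 (adjusted p = 0.0699) and Syce3, of the synaptonemal complex, one of -0.22 (adjusted p = 0.0765). No member passed when adjusted over the list alone. The list's median was -0.072 (-0.13 to -0.020), with an adjusted p of 0.0486 by camera. This call was lost under 8 of 19 alternatives (adjusted p 0.0132 to 0.624), among them camera with an estimated correlation (adjusted p = 0.624), the fit without KO replicate 3 (adjusted p = 0.283, with a median of -0.032) and that without WT replicate 2 (adjusted p = 0.151).

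Genes of undifferentiated spermatogonia were higher in KO. Of 13 measured members 5 rose and none fell (6 rose when adjusted over the list alone), with a median of 0.22 (0.11 to 0.35). Beside Zbtb16, Lin28a rose from 195.8 ± 11.5 to 297.9 ± 12.4 (log2 fold change 0.59, adjusted p = 0.0062), Sall4 from 637.0 ± 32.8 to 800.2 ± 17.5 and Uchl1 from 638.0 ± 26.8 to 770.8 ± 56.8. The adjusted p by camera was 0.00357, and adjusted p = 0.199 with an estimated correlation. The list for differentiating spermatogonia did not pass (adjusted p = 0.312 by camera). It holds Nxf2 itself, whose fall is the knockout. The list did not pass under any of its 19 alternatives, the fit without Nxf2 included (adjusted p 0.075 to 0.624). Of its 14 other members Crabp1 rose by 0.40, Dmrtb1 fell by 0.21 on the log2 scale, and the rest did not pass, Sohlh1 among them (log2 fold change 0.65, adjusted p = 0.0524). Adjusted over the list alone, 6 rose and 3 fell, Nxf2 included.

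Of the somatic lists, those of Sertoli, Leydig and immune cells passed upward by camera, and those of endothelium and peritubular myoid cells did not. All 25 measured Sertoli cell genes had higher means in KO (23 after median centring) and 4 rose (6 when adjusted over the list alone): Drd4 from 101.3 ± 10.9 to 172.9 ± 25.2, Wt1 from 623.1 ± 37.2 to 742.2 ± 17.3, Shbg from 462.8 ± 26.5 to 574.3 ± 47.2 and Inha, the inhibin alpha gene, from 745.6 ± 13.9 to 876.0 ± 55.0. The Sertoli median was 0.21 (0.11 to 0.25), with an adjusted p of 4.42e-05 by camera, and adjusted p = 0.374 with an estimated correlation. All 17 Leydig cell genes had higher means (16 after median centring or quantile normalization) and 2 rose, Star and the lipoprotein receptor gene Scarb1 (8 when adjusted over the list alone). Cyp11a1, which encodes the side-chain cleavage enzyme of steroid synthesis, had a log2 fold change of 0.58 (adjusted p = 0.0553), and Pdgfra, a growth factor receptor gene, one of 0.28 (adjusted p = 0.0575). The Leydig median was 0.32 (0.18 to 0.53), with an adjusted p of 0.00124 by camera, and adjusted p = 0.486 with an estimated correlation. It did not pass by fry either (adjusted p = 0.119). KO replicate 3 stood apart, with a list median of 0.51 relative to the mean of the WT arrays, against 0.19 and 0.23 in KO replicates 1 and 2 and 0.16 in WT replicate 3. Over the alternatives the Leydig median was 0.21 to 0.35. In the list of macrophage and other immune genes none of 25 members passed, also when adjusted over the list alone, but 20 had higher means (19 after median centring or quantile normalization) and the median was 0.43 (0.38 to 0.50). C1qb, a complement gene, had a log2 fold change of 0.64 (adjusted p = 0.0544) and Lyz2, lysozyme, one of 0.53 (adjusted p = 0.0581). This list passed by camera (adjusted p = 0.0102), not with an estimated correlation (adjusted p = 0.624), not by fry (adjusted p = 0.296) and not without KO replicate 3 (adjusted p = 0.054, with a median of 0.21). Relative to the mean of the WT arrays, the list's median was 0.84 in KO replicate 3, 0.30 in KO replicate 2 and 0.11 in KO replicate 1, against 0.18 in WT replicate 3. In the endothelial list, Tek and Robo4 rose by 0.48 and 0.61 (2 of 15, and 2 when adjusted over the list alone), but the list did not pass (adjusted p = 0.0602), except under 4 of 18 alternatives, among them the fit without KO replicate 1 (adjusted p = 0.0121). The peritubular myoid list did not pass either (adjusted p = 0.127, 0 of 15 members, and 0 when adjusted over the list alone): Ptch1 and Cald1 had log2 fold changes of 0.16 and 0.15 (adjusted p = 0.145 and 0.152). The myoid list passed without KO replicate 1 (adjusted p = 0.0469) and without KO replicate 2 (adjusted p = 0.0435).

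Markers of neighbouring tissue moved in both directions. In the fat list Car3 and Fabp4, a fatty acid binding protein gene, rose by 0.95 and 0.80, and Pnpla2, a triglyceride lipase gene, fell by 0.28 on the log2 scale. Of 11 members 2 rose and 1 fell (4 and 1 when adjusted over the list alone), and 8 did not pass, with Thrsp, a lipogenic gene, at a log2 fold change of 0.50 (adjusted p = 0.0699). Cd36, given above, was among those 8 by its brightest probe set, which the list uses. The fat list's adjusted p was 0.0486 by camera, and adjusted p = 0.624 with an estimated correlation. It was lost under 8 of 19 alternatives (adjusted p 0.00506 to 0.624), among them the fits without WT replicate 1 (adjusted p = 0.0574), KO replicate 2 (adjusted p = 0.165) and KO replicate 3 (adjusted p = 0.0608). Of 5 measured epididymal genes 3 fell (5 when adjusted over the list alone): Adam7 by 0.86, Aqp9 by 0.32 and Rnase10 by 0.44 on the log2 scale. The epididymal adjusted p was 0.00179 by camera, and adjusted p = 0.374 with an estimated correlation. Relative to the mean of the WT arrays, the epididymal median was 0.031, -0.40 and 0.24 in WT replicates 1 to 3. The round spermatid list ranked the WT arrays in the same order, but not the KO arrays. In KO replicates 1 to 3 the epididymal median was -0.52, -1.11 and -0.75, and the round spermatid median -1.13, -1.04 and -0.79. Whether these lists share a source was not tested. No skeletal muscle gene of 8 passed, also when adjusted over the list alone (list adjusted p = 0.419), with Actn3 at a log2 fold change of 0.73 (adjusted p = 0.11) and Myh1 at 0.49 (adjusted p = 0.201). The 3 measured red blood cell genes were too few for the list test and none passed, also when adjusted over the list alone. Hba-a2 had a log2 fold change of -0.08 (adjusted p = 0.485) and Alas2 one of 0.46 (adjusted p = 0.519).

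Among the pathways, mRNA export genes other than Nxf2 did not pass. Of the 30 members 29 did not pass, over all genes or adjusted over the list alone, and the list did not pass (median -0.019, -0.068 to 0.023, adjusted p = 0.196 by camera), except without KO replicate 1 (adjusted p = 0.0478). Nxt1, which encodes the NXF cofactor, had a log2 fold change of -0.21 (adjusted p = 0.0807) and Thoc5, of the THO complex, one of -0.19 (adjusted p = 0.0819). In the piRNA and germ granule list, Piwil4 rose by 0.60 and Tdrd7 fell by 0.36 on the log2 scale. The other 18 of its 20 members did not pass, and the list did not pass (median -0.062, adjusted p = 0.073). It passed, downward, without KO replicate 1 (adjusted p = 0.0144), KO replicate 2 (adjusted p = 0.0286), WT replicate 1 (adjusted p = 0.0412) or WT replicate 3 (adjusted p = 0.0497), and without the dim filter (adjusted p = 0.0467). Adjusted over the list alone, 1 rose and 2 fell. In the p53 and apoptosis list 2 of 21 rose (5 when adjusted over the list alone), Pmaip1 by 0.33 and Bcl2l11 by 0.43, which encode proapoptotic BCL2 family proteins. Ccng1, given above, is also a member, but its brightest probe set, which the list uses, did not pass. That list's adjusted p was 0.0382, and adjusted p = 0.374 with an estimated correlation. It was also lost without the intensity trend (adjusted p = 0.0535) and with array weights (adjusted p = 0.0521), in a range of 0.0135 to 0.374 over its alternatives. Of 18 immediate early and tissue handling genes 17 had higher means and 3 rose, Btg2 by 0.76, Jun by 0.46 and Klf6 by 0.24 (4 when adjusted over the list alone). The adjusted p was 0.00181, and adjusted p = 0.52 with an estimated correlation or 0.103 by fry. The mitotic cell cycle list did not pass (adjusted p = 0.634), with Ccna2 raised by 0.43 and Ccnb2 lowered, at a log2 fold change of -0.33, and no other call among 26 (1 and 1 also when adjusted over the list alone). The interferon list did not pass (adjusted p = 0.308), except without WT replicate 3 (adjusted p = 0.0497). None of its 14 members did, also when adjusted over the list alone, with Ddx58 at a log2 fold change of 0.39 (adjusted p = 0.0888) and Ifi27 at 0.15 (adjusted p = 0.284).

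**Figure D2:**
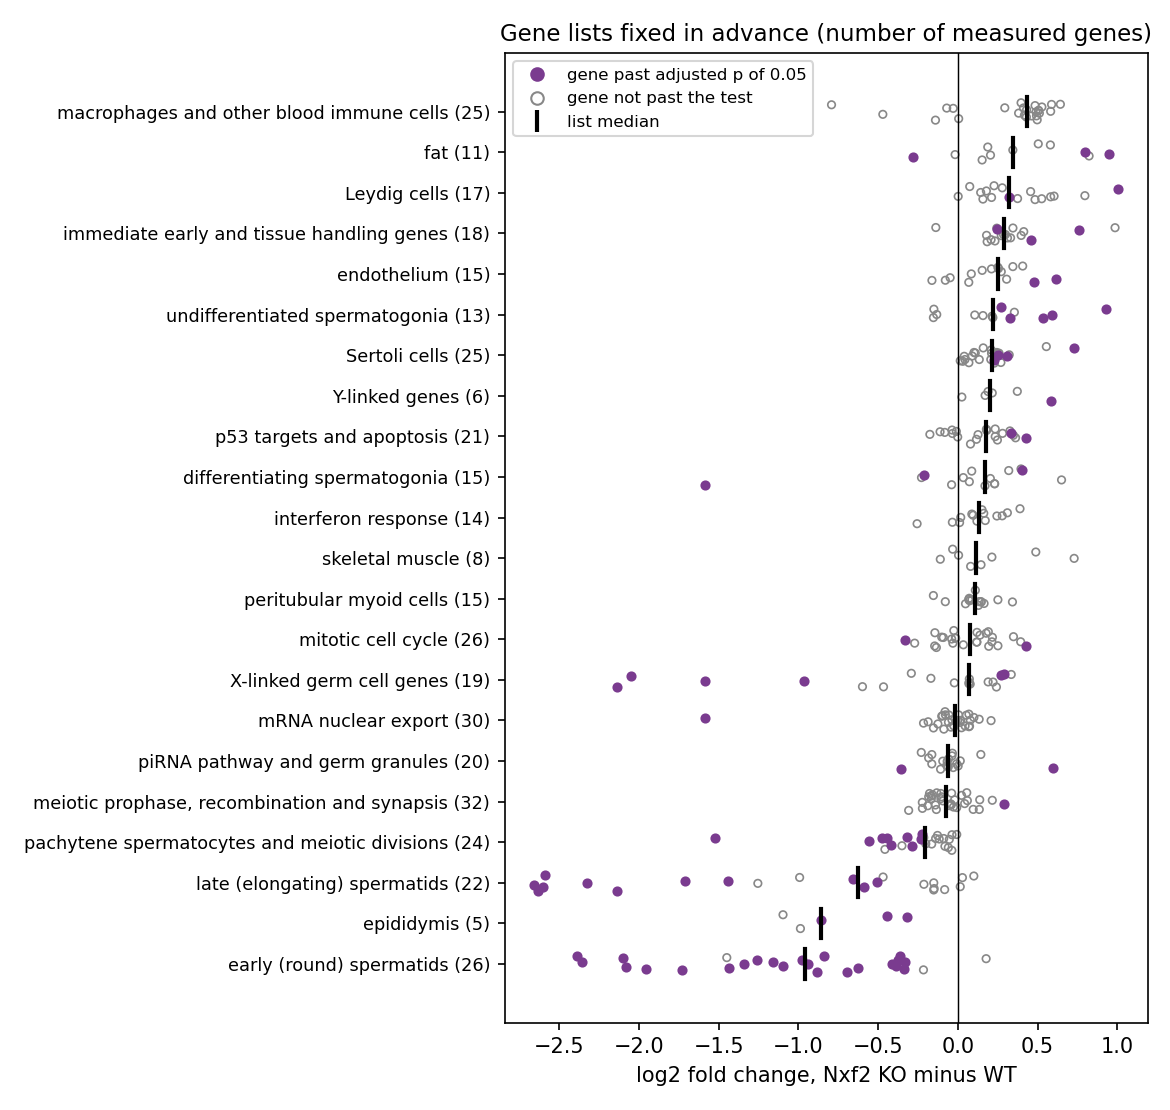
Log2 fold change, KO minus WT, of each measured gene (points) in the 22 gene lists with at least 5 measured genes, filled where the gene passed adjusted p of 0.05, with a black bar at each list's median and the number of measured genes in parentheses. The round spermatid median lies at -0.96 and the Sertoli median at 0.21.

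X-linked genes as a class were higher in KO, a comparison made because the X chromosome is silenced in pachytene spermatocytes and Nxf2 lies on it. Of 429 measured X-linked genes 89.7% had a positive log2 fold change, against 55.8% of 12465 autosomal genes (87.6% and 48.5% after median centring). Their median was 0.24 (0.23 to 0.25), a 1.18-fold rise, against 0.031 (0.026 to 0.035) for autosomal genes, which turned to -0.0072 after median centring. These intervals are over genes and leave out the spread between arrays. With 1 array left out, the X median was 0.18 to 0.27. On the X chromosome 46 genes (10.7%) rose and 14 (3.26%) fell, while on the autosomes 336 (2.70%) rose and 933 (7.48%) fell. Among X-linked germ cell genes fixed in advance, Mageb16 and Tex11 rose by 0.27 and 0.29, whereas Cypt3, Akap4 and Fthl17a fell by 2.05, 2.14 and 0.97 on the log2 scale, as did Nxf2. The Akap4 value here is that of its brightest probe set, and Fthl17a falls outside the rule for named genes and was added after its values were seen. The remaining 13 of the 19 did not pass. Adjusted over the list alone, 6 rose and 7 fell. The median of this list was 0.070 and its mean -0.34, and camera's direction was down (adjusted p = 0.441; down at 0.0156 without the dim filter). Of the 14 X-linked falls, Fam47c, at 48.8 in WT and 5.81 in KO, had the lowest p after Nxf2 and was picked out after its values were seen.

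By camera the X-linked shift had a two-sided p of 5.57e-15, and an adjusted p of 1.17e-13 when every chromosome was tested. With an estimated correlation of 0.370 it did not pass (p = 0.227). No autosome passed (adjusted p = 0.981 for each by camera). The X median relative to that of the autosomes, set against the WT mean, was 0.17, 0.15 and 0.31 in KO replicates 1 to 3 and between -0.052 and 0.052 in the WT arrays. Nor did the Y chromosome pass: of its 8 measured genes 1 rose and 1 fell. Y-linked genes fixed in advance had higher means in 6 of 6 cases (5 after median centring). Kdm5d rose by 0.59 and the other 5 did not pass (3 rose when adjusted over the list alone), with Uty at a log2 fold change of 0.37 (adjusted p = 0.107). That list's median was 0.20 with an adjusted p of 0.0486, and adjusted p = 0.624 with an estimated correlation. It was lost under 8 of 18 alternatives (adjusted p 0.0122 to 0.624), among them the fits without KO replicate 1 (adjusted p = 0.0718), KO replicate 3 (adjusted p = 0.125), WT replicate 1 (adjusted p = 0.0574) and WT replicate 2 (adjusted p = 0.0739).

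**Figure D3:**
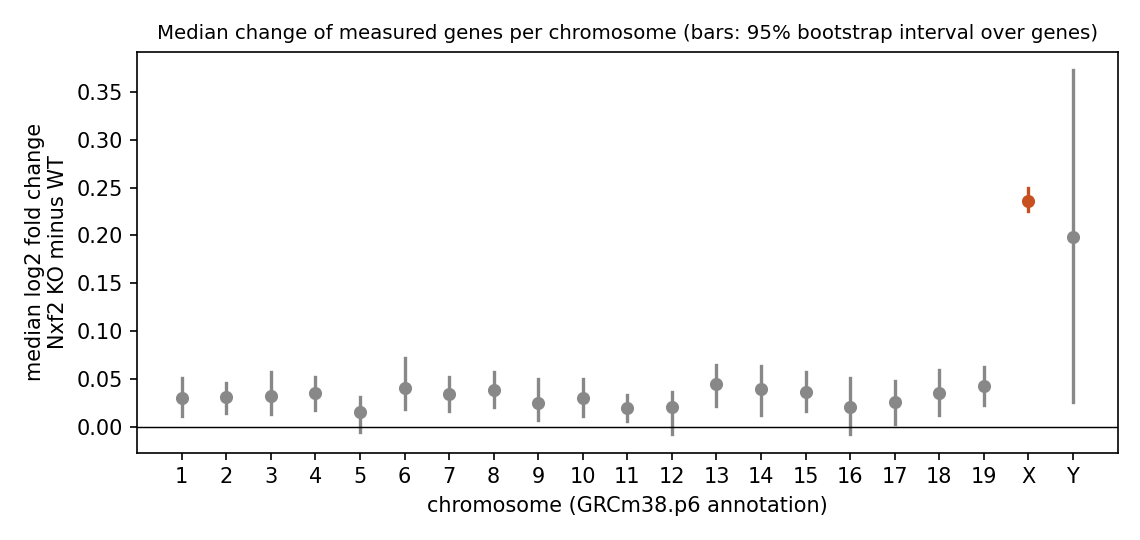
Median log2 fold change, KO minus WT, of the measured genes of each chromosome (points) with 95% bootstrap intervals over genes (bars). The X chromosome lies at 0.24, above every autosome, and the 8 measured genes of the Y chromosome give a wide interval around 0.20.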

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

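The control probe sets, which the comparison above left out, were looked at only after the main results. Among those for mouse genes, 2 passed the test as higher in KO than in WT, and both target the transferrin receptor gene Tfrc. The 3′ one had a signal of 463.5 ± 18.9 in KO against 335.5 ± 16.4 in WT, with a log2 fold change of 0.46 ± 0.059 (SE, limma over the 64 control probe sets, adjusted p = 0.0138). The middle one had 62.9 ± 5.77 against 45.3 ± 2.57 (adjusted p = 0.0467). The regular Tfrc probe sets disagree: 1 rose by 0.45 on the log2 scale (adjusted p = 0.00447), another had a log2 fold change of 0.42 (adjusted p = 0.111) and the remaining 1 had a log2 fold change of 0.032 (adjusted p = 0.794).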

How the results depend on the processing

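The alternatives were planned, except those that left out Nxf2 or 3 distal X-linked genes, which were chosen after seeing the data. No named gene or list that passed a test reversed under any alternative run. Of 343 repeats for the 24 named genes other than Nxf2, 283 kept direction and call and 60 kept the direction only. A gene under the dim filter of a setting has no repeat there. Under the filter at the 60th percentile most of the 24 were not tested, and Akap4 also fell under the dim limit in some fits with 1 array left out. Of 1243 repeats for the genes of lowest p in each list, 977 kept both, 199 lost the call, 64 gained one and 3 moved in direction without a call. Of 414 repeats for the lists, 358 kept both, 40 lost the call, 14 gained one and 2 moved in direction without a call. Nxf2 kept its call throughout (log2 fold change -1.67 to -1.37, adjusted p 1.34e-06 to 0.0114). The 2024 calls, 610 rises and 1414 falls became 1005, 188 and 817 without the dim filter, 743, 174 and 569 without the intensity trend, and 7217, 3771 and 3446 with array weights. Median centring gave 353 rises. Leaving out 1 array gave 164 to 1547 calls, 17 to 388 rises and 147 to 1159 falls, lowest without WT replicate 1; fewer samples enter those fits. Of the 2024 calls, 700 remained without the trend, 910 without the filter, 2015 with array weights and 164 without WT replicate 1. The titles number the samples in each group, and the series' design speaks of 3 pairs of testes, but neither says that a number marks a pair or litter. Deviations of same-numbered arrays correlated at 0.08, 0.46 and 0.27, all above 0. Each KO array correlated best with the WT array of its number, but replicate 1 of WT correlated better with replicate 3 of KO (0.11). The main fit, fixed in advance, did not take the numbers to pair the samples, and a pairing is not excluded. With the number as a replicate block there were 4503 calls, 2173 rises and 2330 falls, among them 2023 of the 2024. Of the 22 lists, 13 passed. With 1 array left out 9 to 16 did, by fry 7, and with an estimated correlation 0 (3 of them at an unadjusted p under 0.05). The 7 by fry were the round and elongating spermatid, pachytene, undifferentiated spermatogonia, Sertoli, epididymis and p53 lists. The X-linked shift had p = 0.227 with an estimated correlation and passed under the other alternatives, with a median of 0.18 to 0.27. The causes of the differences between these settings were not tested. Every fit with 1 array left out has the same number of samples, so that number alone does not account for the range of 164 to 1547 calls. Signals near or under the dim limit bound the precision of the deepest falls.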

Other observations

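The tests in this part were chosen after the main results were seen, as were the genes and families named here, and those of signal level and of the neighbours of Nxf2 were fixed before their own values were computed. Gene families, grouped by the letters that open their symbols, added detail to the falls. Of 210 families with at least 8 measured genes, 15 were lower and 2 higher in KO (camera, adjusted p under 0.05), and none passed with an estimated correlation (adjusted p = 0.992 for each). In the Cfap family, whose members build cilia and flagella, 15 of 23 genes fell and none rose (median -0.39, camera adjusted p = 5.9e-11). Of 18 Spata genes 8 fell, of 10 Spag genes 6, of 10 Efcab genes 6, of 107 Ccdc genes 23 and of 23 Tex genes 8. Ift genes, of intraflagellar transport, had lower means in 13 of 14 cases, and 1 fell. The 2 families that were higher were Tcf, with 3 of 12 genes raised (median 0.28), and Klf, with 2 of 13 (median 0.27). The medians of these families kept their sign after quantile normalization and after median centring.

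Genes still named by RIKEN clones of the 17 and 49 series, in which testis libraries are frequent, fell in 107 of 308 cases (34.7%), and 1 rose. Genes named by clones of other RIKEN series fell in 24 of 281 cases (8.54%), and other genes in 825 of 12382 (6.66%). The difference between the RIKEN series (Fisher's exact test, two-sided p = 4.97e-15, with genes not independent) was tested on the same genes in which it was noticed.

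The split of the arrays into KO and WT gave 2024 calls, and the highest count of the other 9 splits was 0, so 1 of the 10 splits gave as many. With 10 splits the share cannot go under 0.1, which is too few for a share under 0.05.

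The first pattern is the fall of spermatid genes beside the higher lists of Sertoli, Leydig and immune cells and of undifferentiated spermatogonia, while those of differentiating spermatogonia, peritubular myoid cells and endothelium did not pass. A difference in array scaling would move every list the same way, but the Sertoli median exceeded the round spermatid median by 1.17 (0.77 to 1.57). A smaller share of spermatids, with every other cell type raised alike, is argued against, since it would raise early spermatocyte genes as well: the Sertoli median exceeded that of meiotic prophase genes by 0.28 (0.18 to 0.36), with 0.15 to 0.45 in the KO arrays and at most 0.013 in the WT arrays. A smaller share of both spermatids and spermatocytes remains possible: the 7 medians of somatic and spermatogonial lists spanned 0.32, from 0.11 (peritubular myoid) to 0.43 (immune), more than shuffled genes did (permutation p = 0.0283), but the difference of those 2 lists was 0.055, 0.25 and 0.58 in the KO arrays and up to 0.16 in the WT arrays, so the arrays overlap. A later first wave and a loss of germ cells from the spermatocytes on cannot be told apart at 1 age. Both predict the deeper fall of the round spermatid list (0.75 below the pachytene list, a difference of -0.75). Lower expression within the germ cells present and a difference in handling or dissection were not tested. By camera, however, the list of immediate early and tissue handling genes passed upward (0.22 to 0.44 in the KO arrays, at most 0.083 in the WT arrays). The fat list also passed upward by camera and the epididymal list downward. With an estimated correlation none of these passed (adjusted p = 0.52, 0.624 and 0.374 in this order). The fat medians of the arrays overlapped, with 0.132 in KO replicate 1 and 0.135 in WT replicate 3.

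The second pattern is the rise of X-linked genes. A bias with signal level is argued against: the X median of 0.24 lay above 100% of 10000 random autosomal lists matched on mean signal, the highest of which had 0.097. Carried-along DNA limited to the 40 measured genes nearest to Nxf2 is argued against as the whole cause. Without them the X median was 0.23 (0.22 to 0.25), and their own median was 0.27 (0.23 to 0.31). A longer carried-along stretch of the X was not tested, and no label gives the strain. A smaller share of cells with a silenced X, such as pachytene spermatocytes and spermatids, is a candidate explanation: X-linked genes exceeded 22 autosomal Sertoli markers by 0.026 (-0.011 to 0.135). That comparison depends on the list used and does not decide the question. The peritubular myoid median, 0.11 (0.072 to 0.15), lay below the X median and the immune median, 0.43 (0.38 to 0.50), above it. Incomplete silencing in KO spermatocytes would also raise the X above the autosomes (by 0.21, 0.19 to 0.22). It cannot be told apart from a smaller share of cells with a silenced X in RNA of whole testes.

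The third pattern is local: the 3 genes with the largest rises were G530011O06Rik (log2 fold change 2.75 ± 0.526, SE, adjusted p = 0.0169, its clone name kept it out of the rule for named genes), Mid1 and Erdr1, and all 3 lie within 5 consecutive genes of the GRCm38.p6 annotation at the distal end of the X, at the pseudoautosomal region. The lowest of the 3 rose by 1.55 and the upper end of the central 95% of X-linked genes was 0.57, but the 3 were picked for the size of their rise, so these values do not decide whether they are part of the general X-linked shift. The nearby Msl3 rose by 0.47, and Hccs had a log2 fold change of 0.17 (adjusted p = 0.116). A strain difference at that end of the X may be the source: the WT arrays differed widely, with G530011O06Rik at 87.5, 7.39 and 39.9 and Erdr1 at 365.0, 127.4 and 202.8. No label gives the strain, so this and an effect of the genotype cannot be told apart.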
